A study of Homo sapiens with 12 samples.

How the data were processed

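The series holds 12 libraries of poly(A) or total RNA, which the labels do not specify, prepared with NEBNext Ultra kits from Trizol extracts of nuclear and cytoplasmic fractions of HEK293T cells 48 h after Lipofectamine transfection with SF3B1 WT or K700E plasmids. The deposited files give raw counts per gene, 1 file per library, and the authors name HISAT2 and DESeq without versions. The counting program, the genome build and the annotation behind the counts are not given in the sources used here. Values were whole numbers, different in every library, in 67049 gene IDs per file. Files on reads, junctions and splicing are not used here, so mis-splicing was not analysed here.

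IDs were matched without their version number to gene symbols (60507 IDs) and to GENCODE release 29 on GRCh38 for type, length, GC content and position (58440 IDs, holding 99.7% of counts). Coordinates are those of that annotation. Groups were formed by construct and fraction with 3 libraries each. Differences were tested in R 4.3.3 with edgeR 4.0.16, using quasi-likelihood F tests on all 12 libraries in a design with 1 term per group, TMM scaling and filterByExpr (minimum count 10, minimum total 15), which left 20394 genes. Benjamini-Hochberg adjusted p under 0.05 was called. Fold changes are log2 with a standard error (SE), levels are TMM-scaled CPM with the standard deviation of 3 libraries, and the prior count for logarithms was 2. The 5 comparisons were cytoplasm against nucleus with WT, the same with K700E, K700E against WT in the nucleus, the same in the cytoplasm, and the interaction, which is the change of the cytoplasm-to-nucleus ratio. Replicate numbers were not used as a block.

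Before the data were examined, 27 gene lists, 1 of them by symbol pattern and the rest with 854 genes by name, of which 850 were matched, were fixed together with the tests, the alternatives and the rule for named genes. Lists with at least 5 genes tested, 26 of 27, were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, which called 21, 22, 0, 0 and 0 lists in the 5 comparisons, and adjusted over 26 lists. The blood cell marker list had fewer than 5 genes tested. Fry tests whether members move 1 way on balance and does not compare them with other genes. The rule for named genes took, for the cytoplasm-against-nucleus comparisons, the 8 genes with the largest fold change each way among called genes with a mean of at least 5 CPM, an official symbol and groups that do not overlap. For comparisons with fewer than 5 called genes it took the 10 with the smallest p, where the same CPM and symbol conditions were applied, and in all comparisons up to 4 members of each list with a called member or a call, and SF3B1, the THO genes, ALYREF, NXF1, MALAT1 and NEAT1. Of up to 4 list members some are printed, and results of some single genes are not reported here.

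Levels of SF3B1, mitochondrial mRNAs and nuclear-retained RNAs were compared by two-sided exact permutation of 3 against 3 libraries. Library totals ran from 9086743 to 18116929 counts, with the 20 most abundant genes taking 3.71% to 8.10% of them, and the biological coefficient of variation was 0.306. Counts against a group at 0 were bounded with a floor of 3 counts over the group, and ratios with 1 to 3 counts have an exact 95% Poisson interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules. The pipeline was tested on simulated counts with known changes, where edgeR made 1 to 7 false calls per comparison. A list of 27 genes shifted 1.5-fold was called (adjusted p = 9.63e-13), and 0 of 26 unshifted lists were. Genes were simulated independently of each other, so the simulation does not show how often lists are called falsely in the real libraries. There, other splits of the libraries gave up to 11 called lists in the nucleus and 9 in the cytoplasm.

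Alternatives were DESeq2 1.42.0 size factors and its Wald test, limma 3.58.1 voom, library size alone, upper quartile factors, no filter beyond 1 count, a filter of 1 CPM in all 12 libraries, a minimum fold of 2, only the 6 libraries compared, blocks by replicate number or by construct and number together (which the labels do not state to be 1 culture), each library left out, and the set tests above. A correction of each library's trend with transcript GC content, the removal of the 3 libraries whose values rose most with GC content, and an exact permutation of whole libraries on list means were added after the data were seen.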

Results

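RNA was sequenced from the nuclei and from the cytoplasm of HEK293T cells, a line derived from human embryonic kidney, 48 h after transient transfection with a plasmid encoding SF3B1. SF3B1 is a subunit of the U2 snRNP that takes part in the choice of the branch point and 3′ splice site. K700E is a recurrent substitution in blood cancers. The plasmid carried either the wild type (WT) or the K700E sequence. Each construct and fraction was represented by 3 libraries, 12 in all. Total counts per library ran from 9086743 to 11200562 in the nucleus and from 13422598 to 18116929 in the cytoplasm. Between 30007 and 32017 genes had at least 1 count in nuclear libraries, against 23263 to 24210 in cytoplasmic ones. The series title names export of mRNA from the nucleus and the interaction of SF3B1 with THOC5, a subunit of the THO complex that couples transcription to mRNA export. The labels do not say that the 3 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

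SF3B1 mRNA (ENSG00000115524.17, chromosome 2, 197389784 to 197435091 on GRCh38) was abundant in every library. Its level was 9430 ± 1061 CPM (TMM-scaled; SD, n = 3) in WT cytoplasm and 7924 ± 882 in K700E cytoplasm, against 1577 ± 784 and 1600 ± 500 in the matching nuclei. Gene-level counts do not part plasmid-derived from endogenous SF3B1 mRNA, and no untransfected or empty-vector sample is in the series. The 13 mitochondrially encoded mRNAs, which are made outside the nucleus, summed to 12340 ± 7260 CPM in WT cytoplasm and 1096 ± 165 in WT nuclei, and to 6802 ± 601 and 1078 ± 147 CPM with K700E. The 10 measured nuclear-retained long non-coding RNAs, among them MALAT1 and NEAT1, went the other way: 462 ± 37.6 CPM in cytoplasm against 6058 ± 1774 in nuclei with WT, and 497 ± 56.97 against 7260 ± 3619 with K700E. Each of these fraction differences separated all 3 libraries of one fraction from all 3 of the other, which in an exact two-sided permutation test of 3 against 3 gives p = 0.1, the smallest value that design allows (adjusted p = 0.182 over 20 such tests).

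**Figure D1:**
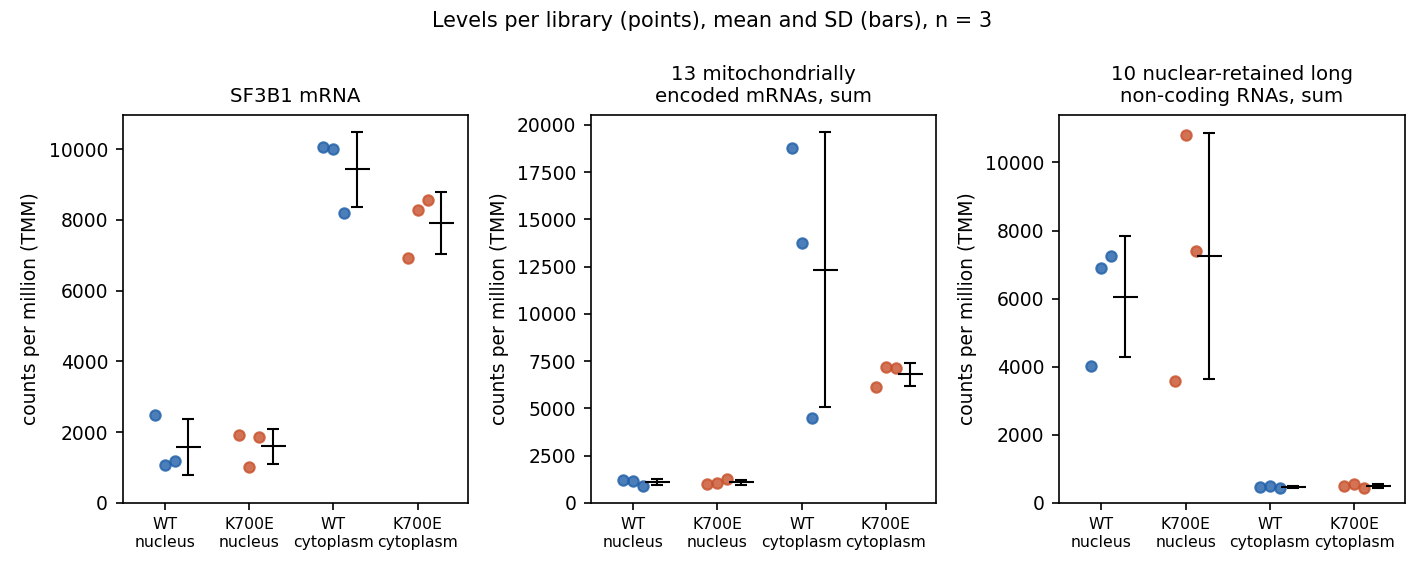
CPM (TMM-scaled, linear axis) of SF3B1 mRNA, of the sum of 13 mitochondrially encoded mRNAs and of the sum of 10 nuclear-retained long non-coding RNAs in each of the 12 libraries. Points are libraries, WT in blue and K700E in orange, and bars give the mean and SD of 3 libraries.

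The first comparison asked how RNAs were distributed between cytoplasm and nucleus in cells given WT SF3B1. Most mRNAs of ribosomal proteins, the respiratory chain and the proteasome were more abundant in the cytoplasm, and most long non-coding RNAs and small nuclear and nucleolar RNAs more abundant in the nucleus. TUBA1B, an alpha-tubulin, was 39.6-fold higher in the cytoplasm (log2 fold change 5.31 ± 0.54 SE, n = 3 per group, edgeR adjusted p = 5.7e-07; 660 ± 230 CPM against 16.6 ± 12.1). At the other end KCNQ1OT1, a long non-coding RNA that silences genes at its own locus, was 212-fold lower in the cytoplasm (-7.73 ± 0.64, edgeR adjusted p = 9.19e-08), MALAT1 71.3-fold lower and NEAT1, the scaffold of paraspeckles, 21.1-fold lower. Of 20394 genes tested, 5513 were higher and 8163 lower in the cytoplasm at an adjusted p under 0.05. By type these were 4905 higher and 4102 lower of 13888 protein-coding genes, 125 higher and 2459 lower of 3710 long non-coding RNAs, and 1 higher and 175 lower of 195 small nuclear or nucleolar RNAs.

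The other mRNAs with the largest cytoplasmic excess were TUBB4A (4.83 ± 0.35), FKBP1C (4.65 ± 0.56), TUBA1C (4.49 ± 0.47), SDHC (4.44 ± 0.33), a subunit of succinate dehydrogenase, the mitochondrial MT-ND4L (4.44 ± 0.51), MARCKSL1 (4.37 ± 0.31) and the polyubiquitin gene UBB (4.32 ± 0.26). FKBP1C and the tubulin genes have close paralogs or processed copies, so their counts depend on how shared reads were assigned. ASPN, SHOC1 and SND1-IT1 had 0 counts in the WT cytoplasm and, against a floor of 3 counts over the group, were at least 249.8-fold, 239-fold and 204-fold lower there. TRIM54 had 1 count in the WT cytoplasm and 529 in the nucleus, a ratio of 580.4 with a counting interval of 104 to 22923. The antisense RNAs ANK2-AS1 (-6.89 ± 0.92) and HMGA2-AS1 (-6.85 ± 0.65) were lower too. TSIX, another antisense gene, also met the rule for named genes, and its value is left out because it overlaps a gene on the opposite strand. Whether counting used the strand is not stated, so values of genes that overlap others may hold reads of those genes. Antisense and intronic genes, SND1-IT1 among them, are such genes. Overlaps were not checked for ASPN, SHOC1 and TRIM54, so their nuclear counts need not come from their own mature mRNA. SF3B1 mRNA was 5.98-fold higher in the cytoplasm (2.58 ± 0.32). Among export factors THOC3 (2.498 ± 0.338), THOC7 (2.35 ± 0.26) and the adaptor ALYREF (2.61 ± 0.30) were higher. THOC5 was also higher (0.95 ± 0.21, edgeR adjusted p = 0.00094). THOC1 (-1.76 ± 0.21) and THOC2 (-1.05 ± 0.24) were lower. THOC6 (-0.80 ± 0.40, adjusted p = 0.0886) and the export receptor NXF1 (-0.33 ± 0.24, adjusted p = 0.232) did not pass. The call of THOC5 ended when only library size was used for scaling (0.42, adjusted p = 0.106).

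Gene lists fixed before the files were opened gave the same picture by pathway, with 18 of 26 lists called by camera at its preset correlation and 0 with an estimated one. For cytosolic ribosomal proteins, 72 of 76 mRNAs were higher and 3 lower (median log2 fold change 2.66, adjusted p = 7.8e-35; adjusted p = 0.117 with an estimated correlation), such as RPS23 (3.59 ± 0.24) and RPL14 (3.30 ± 0.23). All 13 mitochondrially encoded mRNAs were higher (median 3.18, adjusted p = 1.17e-07; adjusted p = 0.236 with an estimated correlation), such as MT-CO2 (4.17 ± 0.34). Of 69 nuclear-encoded respiratory chain mRNAs 52 were higher and 5 lower (1.95, adjusted p = 2.18e-15; adjusted p = 0.103 with an estimated correlation), such as COX6B1 (3.35 ± 0.25). Proteasome subunits (25 higher and 2 lower of 31, median 1.44; PSMB2 3.64 ± 0.23; adjusted p = 0.165 with an estimated correlation) were called higher. So were the ER translocon and glycosylation list (27 and 1 of 37, median 1.56; OST4 3.25 ± 0.27; adjusted p = 0.165 with an estimated correlation) and heat shock chaperones (15 and 2 of 18, median 1.69; HSP90AB1 3.16 ± 0.23; adjusted p = 0.103 with an estimated correlation). DNA replication genes (31 and 6 of 47, median 1.13; GINS2 2.80 ± 0.21; adjusted p = 0.0829 with an estimated correlation) had the same direction. Glycolysis and hypoxia genes (16 and 5 of 33, median 0.61; PGAM1 3.66 ± 0.26; adjusted p = 0.165 with an estimated correlation) and the SF3 complexes with U2 snRNP (15 and 4 of 24, median 1.01; SF3A1 2.61 ± 0.21; adjusted p = 0.0903 with an estimated correlation) were called higher as well.

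Lists with members on both sides were also called higher. TREX and mRNA export factors had 15 members higher and 7 lower of 30 (median 0.56; ERH 2.94 ± 0.25; adjusted p = 0.103 with an estimated correlation). The unfolded protein and integrated stress response had 17 and 5 of 28 (1.02; PDIA6 2.29 ± 0.26 but ASNS, the asparagine synthetase gene, -4.95 ± 0.49; adjusted p = 0.341 with an estimated correlation). Immediate early genes had 11 and 3 of 29 (0.62; JUN 2.17 ± 0.27; adjusted p = 0.412 with an estimated correlation). Cholesterol synthesis had 12 and 4 of 24 (0.81; PMVK 3.47 ± 0.33; adjusted p = 0.165 with an estimated correlation), and heme synthesis and iron handling 11 and 5 of 26 (0.43; FTL 3.18 ± 0.31; adjusted p = 0.165 with an estimated correlation). Mitosis had 24 and 10 of 50 (0.47; BIRC5 2.97 ± 0.23 but CENPE -1.87 ± 0.24; adjusted p = 0.462 with an estimated correlation). The p53 targets had 11 and 4 of 26 (0.51; TRIAP1 2.56 ± 0.29; adjusted p = 0.554 with an estimated correlation). A filter of 1 CPM in all 12 libraries ended the calls of all lists in this paragraph (camera adjusted p from 0.210 to 0.461). It also ended those of the SF3 and U2 (0.0667) and glycolysis and hypoxia lists (0.0927). Camera compares members with all genes tested, and 3710 of these were long non-coding RNAs with a median of -2.59, against 0.13 for protein-coding genes. The mitosis and p53 calls ended when only library size was used for scaling (adjusted p = 0.0521 and 0.0597). The p53 call also ended without nuclear library 3 (adjusted p = 0.107) and without cytoplasmic library 1 (adjusted p = 0.0522) of WT.

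Lists called lower in the cytoplasm were nuclear-retained long non-coding RNAs and detained-intron genes, whose polyadenylated transcripts are known to keep introns in the nucleus. Of 10 nuclear-retained RNAs 8 were lower (median -2.36, adjusted p = 0.000155; adjusted p = 0.0829 with an estimated correlation), such as FTX (-4.32 ± 0.29). Of 27 detained-intron genes 21 were lower and 2 higher (median -1.28, adjusted p = 0.000155; adjusted p = 0.303 with an estimated correlation), such as RBM5 (-2.88 ± 0.24), OGT (-2.40 ± 0.22), NKTR (-2.31 ± 0.23) and SRSF11 (-2.36 ± 0.24). Among lists not called, double-strand break repair genes had 8 members higher and 20 lower of 44 (adjusted p = 0.364), with ATM at -2.03 ± 0.21. The list of snoRNA host and cytoplasmic long non-coding RNAs had 6 higher and 5 lower of 15 (median -0.27 but mean 0.18, adjusted p = 0.4), with SNHG16 at 2.99 ± 0.34 and SNHG5 at -2.23 ± 0.30. SF3B1-mutant splice targets had 7 higher and 9 lower of 25 (median 0.05 but mean -0.13, adjusted p = 0.808), and zinc-finger genes 118 and 113 of 442 (median 0.04 but mean -0.10, adjusted p = 0.4). Interferon-stimulated genes had 8 and 6 of 24 (adjusted p = 0.29), NF-kappaB targets 3 and 5 of 17 (median -0.09, though camera ranked them upward, adjusted p = 0.623), replication-dependent histones 7 and 0 of 24 (adjusted p = 0.0551), and fibroblast and matrix markers 2 and 4 of 7 (adjusted p = 0.48). Adjusted over the list alone, the counts of all these lists differed by at most 1 gene in each direction, except zinc-finger genes with 110 higher and 110 lower. The split between higher and lower genes depends on scaling and filter, since library size alone gave 3775 higher and 10260 lower genes, with the median of all genes shifted by -0.52, and a filter of 1 CPM in all libraries gave 3863 and 4068.

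The second comparison repeated this in cells given K700E SF3B1. Again most mRNAs of ribosomal proteins, the respiratory chain and the proteasome were more abundant in the cytoplasm, and most long non-coding RNAs more abundant in the nucleus. TUBA1B was 36.6-fold higher in the cytoplasm (5.19 ± 0.54 SE, n = 3 per group, edgeR adjusted p = 6.69e-07; 602 ± 230 CPM against 16.4 ± 8.65) and KCNQ1OT1 149-fold lower (-7.22 ± 0.62). TUBB4A (4.96 ± 0.36), RAB3D (4.69 ± 0.48), TUBA1C (4.55 ± 0.47), EIF4EBP1 (4.4998 ± 0.4992), an inhibitor of cap-dependent translation, MRPS28 (4.44 ± 0.44), UBB (4.32 ± 0.26) and NHP2 (4.32 ± 0.31) completed the mRNAs with the largest cytoplasmic excess. On the nuclear side SHOC1, with 0 cytoplasmic counts, was at least 213-fold lower in the cytoplasm, and GNRH1 had a log2 fold change of -6.97 ± 0.46. PRG4, HMGA2-AS1, ANK2-AS1 and SND1-IT1 had 1 or 2 cytoplasmic counts, with ratios of 409, 272, 309 and 189 and lower ends of the counting interval of 113, 75.2, 55.4 and 52.4. Their upper ends were 3379, 2244, 12193 and 1562, and TSIX again met the rule. Overlaps with other genes were not checked for SHOC1, GNRH1 and PRG4, so their nuclear counts have the same limit as above. Of 20394 genes, 5716 were higher and 7724 lower in the cytoplasm, against 4211 and 9458 with library size alone and 3947 and 3923 with a filter of 1 CPM in all libraries. In edgeR with TMM scaling these were 5059 higher and 3800 lower among protein-coding genes and 164 higher and 2392 lower among long non-coding RNAs.

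SF3B1 mRNA was 4.95-fold higher in the cytoplasm of K700E cells (2.31 ± 0.32). THOC3 (2.65 ± 0.34), THOC7 (1.96 ± 0.25), ALYREF (2.57 ± 0.30) and THOC5 (1.19 ± 0.21, edgeR adjusted p = 0.000147) were higher. THOC1 (-2.26 ± 0.21), THOC2 (-1.48 ± 0.24), MALAT1 (-6.26 ± 0.60) and NEAT1 (-4.14 ± 0.29) were lower. THOC6 (-0.22 ± 0.40, adjusted p = 0.65) and NXF1 (-0.38 ± 0.24, adjusted p = 0.18) did not pass. Camera called 16 of 26 lists, 14 higher and 2 lower, and 0 with an estimated correlation. Ribosomal protein mRNAs had 72 members higher and 3 lower of 76 (median 2.93; adjusted p = 0.113 with an estimated correlation). Respiratory chain mRNAs had 54 and 2 of 69 (1.88; adjusted p = 0.113 with an estimated correlation) and proteasome mRNAs 23 and 3 of 31 (1.17; adjusted p = 0.183 with an estimated correlation). All 13 mitochondrially encoded mRNAs were higher (median 2.29; MT-CO2 3.41 ± 0.33; adjusted p = 0.308 with an estimated correlation). Detained-intron genes had 24 members lower and 1 higher of 27 (median -1.94, adjusted p = 6.77e-10; adjusted p = 0.13 with an estimated correlation), with OGT at -3.11 ± 0.23, RBM5 at -3.16 ± 0.24 and SRSF11 at -3.06 ± 0.25. The p53 (adjusted p = 0.0522) and mitosis (adjusted p = 0.0546) lists were not called with K700E. A strict filter on low counts ended the calls of the SF3 and U2, immediate early, unfolded protein, cholesterol and heme lists (camera adjusted p from 0.110 to 0.388). The TREX list, with 13 members higher and 7 lower of 30 (median 0.47; adjusted p = 0.13 with an estimated correlation), lost its call with library size alone (adjusted p = 0.0803), with upper quartile factors (0.0786) and with a strict filter on low counts (0.322).

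The fraction differences were compared between constructs over all genes. Of the genes called, 4910 were higher and 7033 lower in the cytoplasm with both constructs and 6 went opposite ways, while 1727 passed with WT alone and 1491 with K700E alone. Across the 20394 genes, which are not independent replicates, the log2 ratios had a Pearson correlation of 0.932 and a slope of 0.916 of K700E on WT. Large differences between fractions, such as those of TUBA1B and KCNQ1OT1, dominate such a correlation, which does not show that the ratios of single genes are equal.

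**Figure D2:**
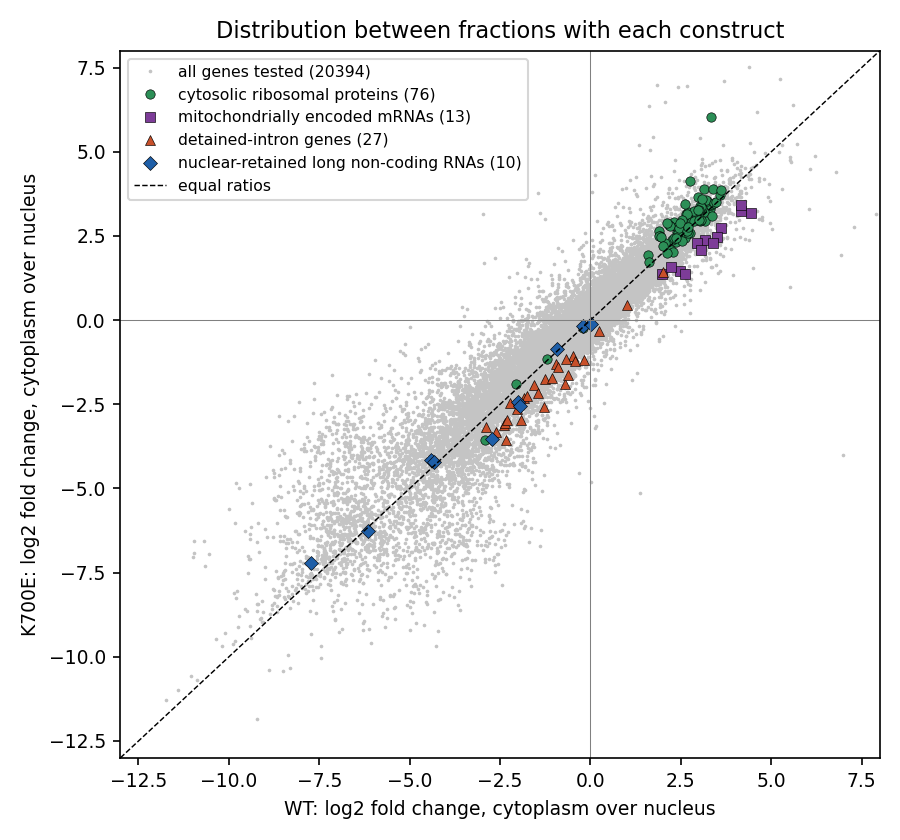
Log2 fold change of cytoplasm over nucleus with WT (horizontal) and with K700E (vertical) for 20394 genes (grey) and the members of 4 gene lists (coloured), with the dashed line at equal ratios. Ribosomal protein mRNAs have medians of 2.66 and 2.93, and detained-intron genes of -1.28 with WT and -1.94 with K700E.

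The third comparison asked whether nuclear RNA differed between K700E and WT. No gene passed in edgeR, so the genes with the smallest p-values are given as values. ARRDC4, an arrestin-domain gene induced by glucose, was at 132 ± 94.0 CPM with K700E and 47.4 ± 5.96 with WT (log2 fold change 1.48 ± 0.39 SE, n = 3 per group, edgeR adjusted p = 0.663), and the glycolytic enzyme PGK1 at 368 ± 78.5 and 200 ± 50.2 CPM (0.88 ± 0.23, adjusted p = 0.663). SRM, a polyamine synthesis enzyme, was at 21.1 ± 6.65 CPM with K700E and 41.3 ± 9.15 with WT (-0.97 ± 0.27). The other genes named by rank, all at adjusted p = 0.663, were GPRIN3 (1.22 ± 0.32), BCHE (1.84 ± 0.52), RNF152 (1.21 ± 0.34), ENDOD1 (1.35 ± 0.38), MTURN (0.88 ± 0.25), TMEM11 (-0.89 ± 0.25) and FAM174C (-1.38 ± 0.40). SF3B1 was at 0.02 ± 0.31 and THOC5 at -0.24 ± 0.21. Among the other named export factors, MALAT1 and NEAT1 the values ran from -0.86 ± 0.40 (THOC6) to 0.39 ± 0.47 (MALAT1).

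No gene passed in edgeR, against 1368 at an unadjusted p under 0.05 and a smallest adjusted p of 0.226. The fit estimates the spread of each gene over all 12 libraries together, and the 95% intervals and simulated counts rest on that shared spread. Yet the coefficient of variation was 0.407 in WT nuclei and 0.199 in WT cytoplasm. With only the 6 libraries compared, edgeR gave 752 genes at an unadjusted p under 0.05 in the nucleus and 1552 in the cytoplasm. limma-voom called 0 and DESeq2 1, UQCRC2, a respiratory chain subunit whose low counts may depend on how reads were divided between copies of the gene (-2.90, 1.23 ± 0.165 CPM with K700E and 9.27 ± 4.89 with WT). For 39.0% of genes the 95% interval of the fold change excluded a 2-fold difference in either direction. In simulated counts with the spread of these libraries the same edgeR test recovered 17% of 2-fold and 65% of 4-fold changes.

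As lists, detained-intron genes were called higher in K700E nuclei (24 of 27 positive, median 0.28, adjusted p = 5.77e-05; adjusted p = 0.935 with an estimated correlation), with PNISR at 0.76 ± 0.30 and TRA2A at 0.53 ± 0.23. That call ended when each library's trend with GC content was removed (0.09, adjusted p = 0.228). Respiratory chain (median -0.21, 52 of 69 negative, adjusted p = 0.00043), ribosomal protein (-0.13, 55 of 76 negative, 0.0263) and proteasome mRNAs (-0.17, 23 of 31 negative, 0.0263) were called lower, each at adjusted p = 0.935 with an estimated correlation. CYC1 (-0.80 ± 0.28), RPL36 (-0.74 ± 0.34) and PSMC5 (-0.63 ± 0.23) are examples. The ribosomal call ended without WT nuclear library 1 (adjusted p = 0.455) or 2 (0.854), and its median was 0.08 without K700E nuclear library 3. The proteasome call ended without WT library 1 (0.703) or K700E library 3 (0.761). The respiratory call ended without K700E library 3 (0.738). No member of a called list passed over all genes, and adjusted over the list alone 1 respiratory chain gene fell.

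The fourth comparison asked the same of cytoplasmic RNA. No gene with a symbol passed in edgeR, so the genes with the smallest p-values are given as values. TXNIP, a glucose-induced regulator of glucose uptake, was at 267 ± 162 CPM with K700E and 72.2 ± 16.05 with WT (log2 fold change 1.89 ± 0.45 SE, n = 3 per group, edgeR adjusted p = 0.787). SLC2A3, a glucose transporter, was at 45.5 ± 8.46 and 20.2 ± 3.57 CPM (1.17 ± 0.28). ANKRD37, induced by hypoxia, was at 8.18 ± 5.85 and 2.10 ± 0.737 (1.95 ± 0.46), and TSC22D3, a glucocorticoid and FOXO target, at 797 ± 82.5 and 391 ± 64.8 (1.03 ± 0.23). EGR1, an immediate early gene, was at 18.2 ± 7.32 CPM with K700E and 47.1 ± 7.43 with WT (-1.37 ± 0.30). The remaining genes named by rank were N4BP2L1 (1.89 ± 0.39), the lipoprotein receptor VLDLR (1.12 ± 0.24), NPR3 (2.05 ± 0.45), SAT1 (1.35 ± 0.31) and RUFY1 (-1.88 ± 0.43), all with adjusted p from 0.692 to 0.787. SF3B1 was at -0.25 ± 0.31, THOC5 at -0.00 ± 0.21, NXF1 at -0.52 ± 0.24 and ALYREF at -0.50 ± 0.28.

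The only gene to pass in edgeR was ENSG00000277104.4, an ID without a symbol or position in the annotation used here and outside the rule for named genes, so chosen after its values were seen. Its level was 1.47 ± 0.197 CPM with WT and 10.3 ± 4.18 with K700E (2.79 ± 0.39, edgeR adjusted p = 0.0404). Whether this ID is a copy of another gene is not known here, so its counts may depend on how shared reads were divided. The call ended in limma-voom (adjusted p = 0.175), which called 0 genes, with a block by replicate number (0.107) and without the 3 libraries whose values rose most with GC content (0.155). It also ended without any of WT cytoplasmic libraries 1, 2 and 3 (0.451, 0.630 and 0.182) or K700E library 3 (0.325). It held in DESeq2 (adjusted p = 3.23e-07), with the other scalings and filters, after GC correction (0.0233), with only 6 libraries and without K700E library 1 or 2. DESeq2 called 13 genes, among them TXNIP, ANKRD37, NPR3, EGR1, RUFY1, VLDLR, N4BP2L1 and TSC22D3, these 8 each at an adjusted p from 0.0358 to 0.0498. At an unadjusted p under 0.05 edgeR had 926 genes, and 1552 with only the 6 cytoplasmic libraries, whose spread was smaller than that of the nuclear ones. For 48.0% of 19825 genes the 95% interval, from the spread shared by all 12 libraries, excluded a 2-fold difference. The edgeR test recovered 13% of 2-fold and 55% of 4-fold changes in simulated counts.

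Camera called 10 lists in the cytoplasm, and none with an estimated correlation. The 13 mitochondrially encoded mRNAs were all negative (median -0.90, adjusted p = 3.83e-13; adjusted p = 0.198 with an estimated correlation), such as MT-ATP8 (-1.44 ± 0.39) and MT-ATP6 (-1.20 ± 0.36), and 8 fell when adjusted over the list alone against 0 over all genes. Beside them the WT cytoplasmic libraries differed among themselves by a log2 range of 2.10 in these mRNAs. Of 27 detained-intron genes 25 were negative (median -0.33, adjusted p = 2.14e-12; adjusted p = 0.145 with an estimated correlation), with the splicing regulators DDX5 at -0.85 ± 0.31 and TRA2B at -0.56 ± 0.20. All 31 proteasome mRNAs were negative (-0.30, adjusted p = 4.1e-09; adjusted p = 0.198 with an estimated correlation). Negative too were 24 of 30 TREX and export factors (-0.22, 0.00123; adjusted p = 0.145 with an estimated correlation) and 20 of 24 members of the SF3 and U2 list (-0.14, 0.00192; adjusted p = 0.145 with an estimated correlation), among them SF3B4 at -0.48 ± 0.26. Heat shock chaperones (-0.31, 15 of 18 negative; DNAJA1 -0.77 ± 0.27; adjusted p = 0.208 with an estimated correlation) and respiratory chain mRNAs (-0.19, 60 of 69 negative; NDUFB2 -0.63 ± 0.27; adjusted p = 0.408 with an estimated correlation) were called lower too. Glycolysis and hypoxia genes were the only list called higher (24 of 33 positive, median 0.19, adjusted p = 5.79e-06; adjusted p = 0.145 with an estimated correlation), with ENO2 at 0.75 ± 0.23 and HK2 at 0.57 ± 0.20, and 3 rose when adjusted over the list alone. The p53 (-0.15, adjusted p = 0.0472) and mitosis lists (-0.14, adjusted p = 0.0451), each at adjusted p = 0.623 with an estimated correlation, lost their calls with library size, upper quartile factors and the strict filter. They were also lost without several single libraries, with adjusted p of 0.413 without K700E library 2 and 0.292 without K700E library 3 at most.

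**Figure D3:**
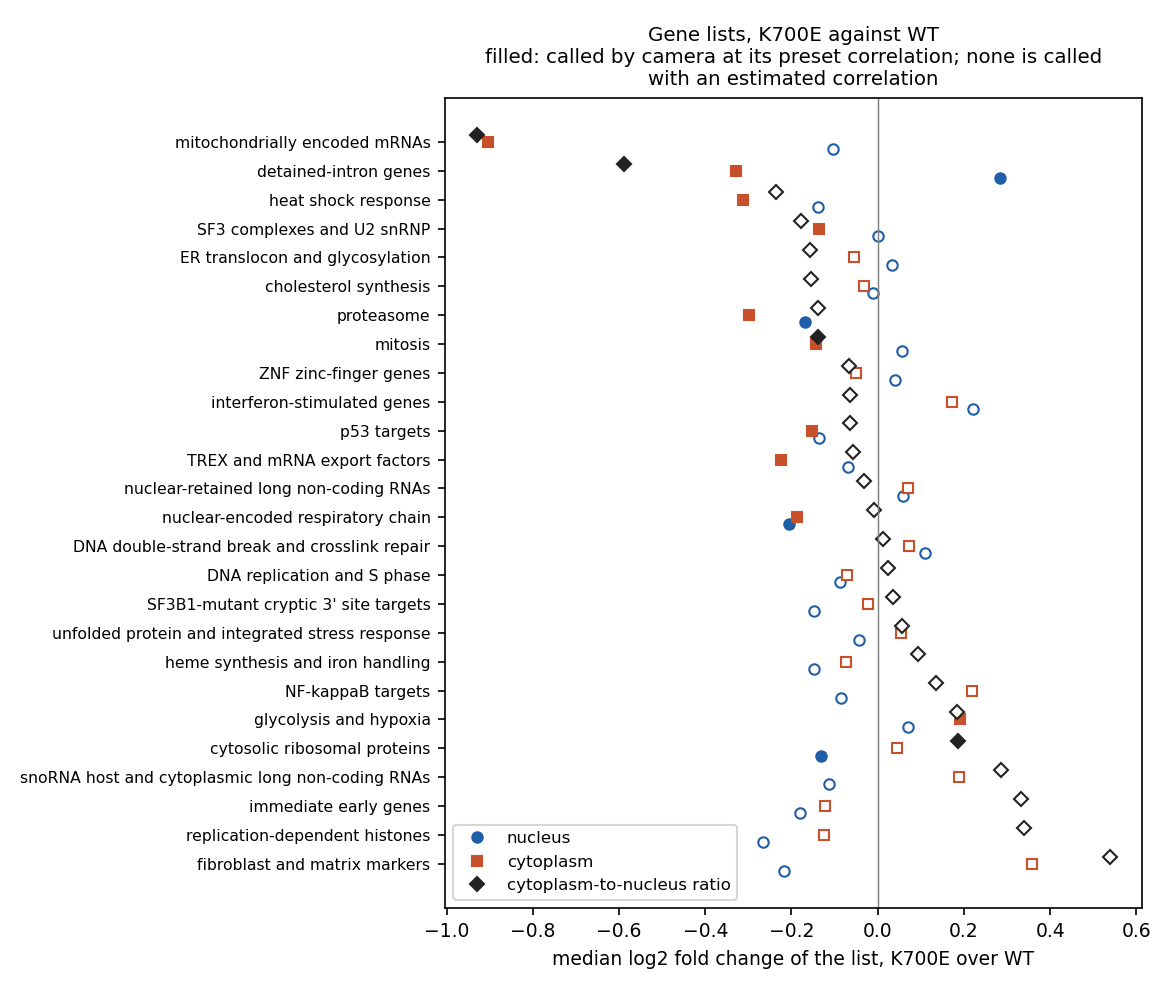
Median log2 fold change of K700E over WT for 26 gene lists in the nucleus (blue circles), the cytoplasm (orange squares) and the cytoplasm-to-nucleus ratio (black diamonds). Filled symbols are lists called by camera at its preset correlation, and 0 lists were called with an estimated correlation.

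The fifth comparison asked whether the cytoplasm-to-nucleus ratio itself changed with K700E, the question closest to mRNA export. Detained-intron genes, which encode mostly splicing regulators, had lower ratios with K700E than with WT, 27 of 27 negative with a median log2 change of -0.59. Members with the smallest p-values were LUC7L3 (-1.22 ± 0.43 SE, n = 3 per group), DDX5 (-1.18 ± 0.43), DDX17 (-1.03 ± 0.35) and TRA2A (-1.005 ± 0.323). The largest change was that of MAT2A (-1.31 ± 0.69). Random lists matched for mean level and mean ratio of the fractions had a median of -0.22, and -0.083 after GC correction (middle 95% from -0.19 to 0.029), where the list was at -0.42 with 26 of 27 negative. They were drawn gene by gene, so their spread leaves out the correlation between members of the list. In the cytoplasm the list's mean log2 CPM relative to all genes was 4.69, 4.78 and 4.60 in the K700E libraries, below the 5.21, 5.17 and 4.99 of the WT libraries. In the nucleus it was 6.11, 6.36 and 6.02 with K700E and 6.19, 5.37 and 5.85 with WT. The nuclear libraries numbered 2, at 6.36 and 5.37, had opposite trends with GC content (Spearman rho -0.630 and 0.630), and lay at 6.06 and 5.74 once the trends were removed. Camera called the list (adjusted p = 4.63e-20; adjusted p = 0.165 with an estimated correlation), and 0 members passed singly, also when adjusted over the list alone. An exact permutation of whole libraries within fractions over 400 relabelings gave a mean change of -0.79 with p = 0.015, and p = 0.39 after adjustment over 26 lists.

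**Figure D4:**
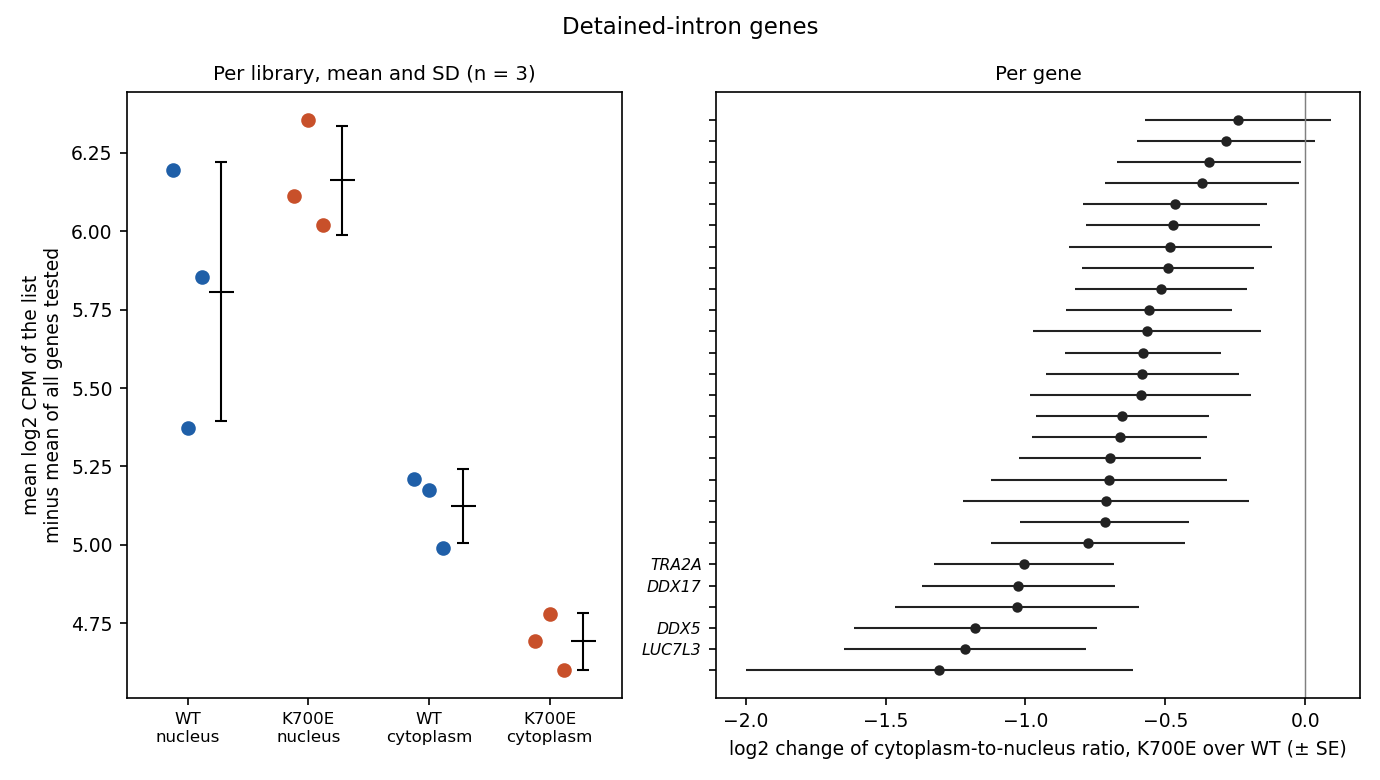
Left, mean log2 CPM of 27 detained-intron genes minus the mean of all genes tested, per library (points), with the mean and SD of 3 libraries. Right, log2 change of the cytoplasm-to-nucleus ratio, K700E over WT, per gene with its SE, the 4 genes of smallest p named; 27 of 27 values are below 0.

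Mitochondrially encoded mRNAs had a median change of ratio of -0.93 (13 of 13 negative, adjusted p = 4.4e-07; adjusted p = 0.751 with an estimated correlation). The lowest WT cytoplasmic library, at a relative mean log2 CPM of 4.82, lay below the lowest K700E one at 5.14. An exact permutation of whole libraries gave p = 0.35 for this list, 0.19 for mitosis genes and 0.6 for ribosomal protein mRNAs (adjusted p = 0.933 for each). Mitosis genes were at -0.14 (32 of 50 negative, 0.0371; adjusted p = 0.91 with an estimated correlation) and ribosomal protein mRNAs 0.19 (59 of 76 positive, 0.0153; adjusted p = 0.931 with an estimated correlation), the latter at -0.04 without K700E nuclear library 3. The mitosis and ribosomal calls ended without several single libraries, with adjusted p of 0.300 without K700E nuclear library 1 and 0.647 without WT nuclear library 2 at most. SF3B1-mutant splice targets were not called (median 0.03, adjusted p = 1), nor were TREX and export factors (-0.06, adjusted p = 0.239). No export factor passed. THOC5 was at 0.24 ± 0.30 with a 95% interval of -0.38 to 0.87, THOC6 at 0.58 ± 0.57, THOC3 at 0.15 ± 0.45, THOC7 at -0.39 ± 0.35, THOC2 at -0.44 ± 0.33 and THOC1 at -0.50 ± 0.29. ALYREF was at -0.04 ± 0.40, NXF1 at -0.04 ± 0.34 and SF3B1 mRNA itself at -0.27 ± 0.43. By rank the genes were RUFY1 (-2.86 ± 0.60), DLG4 (1.61 ± 0.44), PMM1 (1.54 ± 0.42), and MTURN (-1.23 ± 0.35). They were followed by the kinesin KIF15 (-2.51 ± 0.73), the cyclin CCNL1 (-1.11 ± 0.33), JTB-DT (1.4995 ± 0.4507), the lipid droplet gene HILPDA (1.68 ± 0.52), KCNJ4 (2.29 ± 0.71) and the splicing factor SRSF1 (-1.48 ± 0.46), all at adjusted p = 0.981.

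No gene passed in edgeR, with 668 at an unadjusted p under 0.05. limma-voom called 0 and DESeq2 3, RUFY1, UQCRC2 and ENSG00000277104.4. The 95% interval excluded a 2-fold change of ratio for 22.9% of genes, and 4.5% of 2-fold and 42.5% of 4-fold changes were recovered in simulated counts. Values are relative to the other RNAs of the same library and no spike-in was used, so a shift shared by all mRNAs would not appear.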

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

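The GC correction was added after the data were seen, and the test of single libraries for detained-intron genes and all tests of the mitochondrial and glycolysis patterns were chosen after the result was seen, while the random lists and the other splits were set before theirs were computed. The change of the cytoplasm-to-nucleus ratio with K700E had a median log2 value of -0.93 for mitochondrially encoded mRNAs, -0.59 for detained-intron genes, 0.19 for ribosomal protein mRNAs and -0.14 for mitosis genes.

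The lower cytoplasm-to-nucleus ratio of detained-intron genes in K700E kept its direction in the tests of technical causes, with a mean change of -0.58 after GC correction (exact permutation p = 0.02; -0.79 before). With any 1 library left out the median nearest to 0 was -0.47, and of 10000 random lists matched for mean level and mean ratio of the fractions the median was -0.22 and the lowest 2.5% lay below -0.33 (lowest -0.43). A less complete separation of nucleus and cytoplasm would shift matched genes alike, and the list, at -0.59, lay below all matched random lists. These were drawn gene by gene, so their spread leaves out the correlation between members of the list. They therefore cannot decide whether unequal separation is the whole cause. Most of the shift of matched genes went with the GC trend (random median -0.083 after correction, middle 95% from -0.19 to 0.029, list -0.42). In the nucleus alone the list's median was 0.087 after GC correction and 0.041 without the 3 libraries whose values rose most with GC content. Its camera call there ended in both settings (adjusted p = 0.228 and 0.0613). In the cytoplasm alone the mean change was -0.43 before GC correction (exact permutation p = 0.1, adjusted p = 0.289). For the ratio the exact permutation gave p = 0.39 after adjustment over 26 lists, and differences between transfections or harvests were not tested.

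The lower mitochondrially encoded mRNAs in K700E cytoplasm are in line with variation between libraries unrelated to the construct, since the lowest WT cytoplasmic library, at a relative mean log2 CPM of 4.82, lay below every K700E library (5.14, 5.48 and 5.32) while the other WT libraries were at 6.94 and 6.55. Unequal carry-over of mitochondria stays open, because the rRNAs MT-RNR1 (-0.23 ± 0.27) and MT-RNR2 (0.19 ± 0.37) lay outside the range of the mRNAs, -1.44 to -0.65, but may be captured differently. The GC trend of single libraries is no explanation, with a median of -0.95 after correction.

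The higher glycolysis and hypoxia genes in K700E cytoplasm kept a median of 0.21 after GC correction, against 0.19 before. In the nucleus the median was 0.071, which leaves open whether the state of the cultures at harvest, such as glucose or oxygen supply, or the construct lies behind the values of ANKRD37, SLC2A3 and ENO2.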

How the results depend on the processing

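The GC correction, the removal of 3 libraries and the exact permutation were chosen after the data were seen. For cytoplasm against nucleus the strict filter on low counts gave 7931 genes and 10 lists with WT and 7870 genes with K700E. With an estimated correlation 0 lists were called in all 5 comparisons. Library size alone shifted the median of all genes by -0.52 with WT and -0.41 with K700E, and upper quartile factors by -0.38 and -0.37. The cause was not tested.

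For K700E against WT the nucleus had 10 genes without a filter, 1 in DESeq2 and 1 gene and 2 lists without the 3 libraries whose values rose most with GC content. The cytoplasm had 48 genes without a filter, 13 in DESeq2, 0 in limma-voom and 3 without those libraries. The change of ratio had 9 genes and 8 lists without a filter, 3 genes in DESeq2 and 0 lists by exact permutation. With 1 library left out the nucleus had 0 to 1 genes and 3 to 10 lists, the cytoplasm 0 to 2 genes and the ratio 0 to 1 genes and 2 to 7 lists. The cause was not tested.

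A block by replicate number left 13601 genes with WT and 13412 with K700E and 0 in the cytoplasm between constructs. Numbers were not taken to pair the samples, since the labels do not state a pairing. Of 18 pairs with 1 number 5 had a correlation over 0.1, in a range of -0.249 to 0.427. Between WT and K700E libraries of 1 fraction all were positive. They were 0.427, 0.0634 and 0.199 in the nucleus and 0.0269, 0.157 and 0.343 in the cytoplasm for numbers 1, 2 and 3. Another number correlated more for nuclear number 2 (0.129) and cytoplasmic numbers 1 and 2 (0.101 and 0.173). A structure by number within a fraction is therefore not excluded.

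Signs of small values changed, and the cause was not tested. In the nucleus SF3B1 was at -0.0016 with library size, -0.13 after GC correction and -0.20 without the 3 libraries, THOC7 at -0.038 and -0.058 in the latter settings and NEAT1 at 0.035 without the 3 libraries. In the cytoplasm THOC5 was at 0.033 with library size, 0.016 with upper quartile factors, 0.017 after GC correction, 0.028 without the 3 libraries and 0.0048 with only 6 libraries, and NEAT1 at -0.017 without the 3 libraries. For the ratio library size gave ALYREF 0.080, NXF1 0.039 and MALAT1 0.048. MALAT1 was at 0.13 in limma-voom, 0.16 and 0.086 with a block by number and by construct and number together, and 0.17 after GC correction. Without the 3 libraries THOC3 was at -0.16, THOC6 at -0.11 and NEAT1 at -0.052.

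With 1 library left out the ranges were, for THOC6 in K700E cytoplasm against nucleus, -0.70 to 0.18. In the nucleus they were -0.19 to 0.51 (SF3B1), -0.051 to 0.39 (THOC7), -0.22 to 0.80 (MALAT1), -0.42 to 0.040 (NEAT1) and -0.32 to 0.078 (ribosomal proteins). In the cytoplasm they were -0.16 to 0.070 (THOC2), -0.64 to 0.051 (THOC3), -0.070 to 0.078 (THOC5) and -0.79 to 0.038 (THOC6). For the ratio they were -0.28 to 0.41 (THOC3), -0.45 to 0.17 (ALYREF), -0.25 to 0.14 (NXF1), -0.52 to 0.50 (MALAT1) and -0.043 to 0.36 (ribosomal proteins). The cause was not tested.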

Other observations

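The relation with exon number was set before its value was computed, and the genes of both fractions were chosen after the result was seen. TXNIP and its relative ARRDC4, both induced by glucose, had higher values with K700E in the nucleus (1.40 ± 0.44 and 1.48 ± 0.39, edgeR unadjusted p = 0.00589 and 0.00157) and in the cytoplasm (1.89 ± 0.45 and 1.22 ± 0.39). Neither passed after adjustment, and both were picked by hand from the genes at an unadjusted p under 0.05 in both fractions. Of these genes 46 were positive and 39 negative in both, against 13.9 and 16.2 for independent lists, and 10 had opposite signs. Across all genes tested the nuclear and cytoplasmic changes had a Pearson correlation of only 0.0994 (Spearman rho 0.158). Nuclear and cytoplasmic libraries may share cultures, so such an overlap could stem from the cultures. Both comparisons also used the same estimate of spread for each gene, so their p-values are linked. For opposite signs no value for independent lists was computed.

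Whether K700E lowers the cytoplasmic share of transcripts with more exons was tested over 13027 protein-coding genes. The change of ratio had a Spearman rho of 0.00358 with exon number (exact permutation of libraries, p = 0.955). Other relabelings reached an absolute rho of 0.184, so only a large relation could have been told from none. Exon number, length and GC content were those of the longest annotated transcript of each gene, which need not be the transcript expressed. With transcript length rho was -0.177 (exact permutation p = 0.46), and -0.0242 after GC correction, which leaves a relation with length open. The relation with GC content was larger, with rho 0.599 (exact permutation p = 0.28). Its 0.0539 after GC correction tests nothing, since the correction takes out such a trend by construction. The value for length shrank under the same correction, so the trends of single libraries with GC content enter it. With exon number rho was 0.0545 after GC correction (exact permutation p = 0.63).

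Between constructs, other splits of the same libraries show how often such counts arise without the labels. For cytoplasm against nucleus the real splits gave 13676 genes with WT and 13440 with K700E, against at most 0 in others. Lists numbered 18 and 16, against at most 16 and 20. Every other split there mixed both fractions in each group, so the fraction difference became spread within groups. Part of that difference also stayed between the groups, so neither count is a test of the fractions. In addition, 10 splits are too few for a share under 0.05. For K700E against WT the nuclear split gave 0 genes, where another split gave 534, and 4 lists against 11. That split sets WT libraries 2 and 3 and K700E library 3 against WT library 1 and K700E libraries 1 and 2. It parts the libraries numbered 1 from those numbered 3, and on the first principal component, which separates the fractions, they lie at -147, -152 and -151 against -109.5, -119.5 and -132. This points to a structure of the nuclear samples other than the construct, which follows the replicate numbers in part (correlations of 0.427, 0.0634 and 0.199 between nuclear libraries with numbers 1, 2 and 3). Nuclear-retained long non-coding RNAs summed to 4019 (WT) and 3574 CPM (K700E) in nuclear libraries numbered 1, against 6903 to 10807 in the others. K700E library 2, on the same side of that split, had the highest sum. Mitochondrially encoded mRNAs, at 1207 and 969 CPM in the libraries numbered 1, were not high in both. Unequal separation of the fractions may enter here and was not tested. With a block by replicate number the nucleus still had 0 genes. In the cytoplasm the real split gave 1 gene and 10 lists, against at most 2 and 9, and as many genes came in 3 of 10 splits. A real count of 0 is matched by every split, so the gene counts of the nucleus and of the change of ratio (100 of 100 splits, highest other 1) test nothing. For the change of ratio 74 of 100 splits gave at least the real 4 lists (highest other 15), so the number of lists called there is no more than relabeled libraries give. As many lists as the real split came in 7 of 10 nuclear splits.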
